A study of Mus musculus with 4 samples.

How the data were processed

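RNA sequencing had been done on 4 libraries of mouse primary cortical neurons, 1 library for each combination of genotype (wild type or Brg1 conditional knockout, cKO) and treatment (basal KCl or 50 mM KCl for 6 h). Per the labels, cortical neurons came from E16.5 embryos, and TTX (1 µM) and APV (100 µM), which block sodium channels and NMDA receptors, were added on day 5 in vitro before KCl was added on day 6. The authors deposited 1 table with a value for each of 22552 genes in each library. The unit of the deposited values was read from the values themselves as FPKM (fragments scaled to transcript length and library depth), because the labels do not name it: the values are not whole numbers, the 4 columns sum to between 302041 and 330621, and low values lie on small multiples of a step that differs by gene. Whether reads or fragments were counted is not stated, and a further scaling between libraries is not stated either. The submitters' processing notes name TopHat 1.3.2 and the mm9 genome. The program that made the gene values, the gene annotation and the filters are not given in the sources used here.

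Each library was assigned to its group from its label. Depth was approximated from the table, since no counts were used: a single fragment on a transcript of known length gives a fixed FPKM, and the most frequent such step among transcripts longer than 2000 bases, with lengths from GENCODE M21, placed the libraries at about 21300000 (wild type basal), 21400000 (wild type KCl), 22000000 (cKO basal) and 23400000 (cKO KCl) fragments. At these depths 1 FPKM on a transcript of 2 kb corresponds to about 42.5 to 46.9 fragments. The annotation differs from the authors' genome build, so it was used for length, GC content, exon number and chromosome only. Of the 13248 genes retained, 90.5% had a length and 99.4% a chromosome.

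Genes at 1 FPKM or more in at least 1 library were retained (13248 genes). For each gene a log2 ratio was taken after adding 1 to both values, for KCl against basal in each genotype and for cKO against wild type in each condition. The difference in KCl response was the cKO log2 ratio minus the wild-type log2 ratio. With 1 library per group neither a single comparison nor the difference in KCl response leaves a residual degree of freedom, and an additive model of genotype and KCl, which leaves 1, was not fitted. No p-value or standard error is given, and genes were counted by a fixed size of 2-fold on these ratios, and the words higher and lower describe these libraries alone. Folds printed for single genes are ratios of the deposited values. Their 95% intervals (exact binomial on the approximated fragments, conditional on the sum) cover counting error only, not differences between cultures or animals.

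Gene lists were fixed before the data were examined, 25 in all: immediate early genes, late activity-regulated genes, BAF complex subunits, glutamate receptors and postsynaptic proteins, presynaptic proteins, voltage-gated ion channels, excitatory neuron markers, interneuron markers, neuropeptides, sonic hedgehog signalling, progenitor and cell cycle genes, astrocyte, oligodendrocyte and microglia markers, vascular and fibroblast markers, erythroid genes, cholesterol synthesis, glycolysis, endoplasmic reticulum stress, cytosolic heat shock proteins, p53 targets, interferon-stimulated genes, matrix and guidance genes, ribosomal proteins and reference genes. The median log2 ratio of each list was placed among the medians of 10000 random lists with the same number of genes in each of 20 bins of mean level. This describes the list within these libraries and is not a test across animals. Of 120 such placements, 72 fell outside the central 95% of random lists, where 6 would by chance. The placements are not independent, because all comparisons come from the same 4 libraries and some lists share members. The excess over 6 therefore does not measure how many lists differ.

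Single genes were named by a rule also fixed before the data were examined. It took Smarca4, the 10 highest and 10 lowest log2 ratios of each comparison among genes at 5 FPKM or more in the higher library, the 10 most negative and 5 most positive differences in KCl response, up to 4 members of each list with the largest ratios, and Fos, Fosb, Npas4, Arc, Egr1, Bdnf, Nptx2 and Scg2. Unnamed genes, small RNAs and genes that mark sex were left out of the rule, which named 247 genes. Some of these are not reported here. The sex-linked genes, the tubulins Tubb4 and Tubb6, the macrophage gene Lyz2 and the list members Sox2, Hmgcs1, Gapdh and Ppia are outside the rule and were chosen after their values were seen.

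Calculations used Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and plots used matplotlib 3.10.9. The procedure was tested on simulated data with Poisson counting at the approximated depths. In each comparison 100 of 100 genes set 4-fold higher and 100 of 100 set lower were recovered. These genes were drawn only from those with a mean of 5 FPKM or more, where full recovery under counting error alone was near certain. Recovery of genes at lower levels was not examined. Counting alone placed 14 to 24 of the unchanged genes past the 2-fold size. The alternatives chosen in advance were added constants of 0.1 and 5, no filter, a filter of 5 FPKM, rescaling by the median ratio, by the upper quartile or by the ribosomal list, and sizes of 1.5-fold and 4-fold. Rescaling to the presynaptic list, leaving out X and Y genes, leaving out unnamed genes and small RNAs, and choosing KCl-responsive genes on the cKO response or on the mean of both responses were added after seeing the data.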

Results

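Gene expression was measured by RNA sequencing in primary mouse cortical neurons that were wild type or carried a conditional knockout of Brg1 (Smarca4), the ATPase of the BAF chromatin remodelling complex. In the knockout (cKO), per the labels, floxed Brg1 alleles were combined with BAF53bCre, a recombinase driven by a neuronal gene. Cultures of each genotype were kept at basal KCl or depolarized with 50 mM KCl for 6 h, a treatment that opens voltage-gated calcium channels and switches on activity-dependent genes. There were 4 groups with 1 library each, so there were no replicates and no difference could be set against a spread between cultures. The FPKM values summed to 306649 in the wild-type basal library, 330621 in the wild-type KCl library, 302041 in the cKO basal library and 330552 in the cKO KCl library, and the approximated depths were 21300000, 21400000, 22000000 and 23400000 fragments. Of 22552 genes, 13248 reached 1 FPKM in at least 1 library.

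Smarca4 was measured at 34.0 FPKM in the wild-type basal library, 28.5 in the wild-type KCl library, 10.5 in the cKO basal library and 10.4 in the cKO KCl library. It was 3.25-fold lower in the cKO at basal KCl (95% counting interval 3.07 to 3.45) and 2.75-fold lower after KCl (2.59 to 2.91). The other BAF subunits differed less between genotypes: 26 of the 27 measured subunits lay within 2-fold in both genotype comparisons, Smarca4 being the exception, and Smarca2, the alternative ATPase, stood at 63.6 FPKM in wild type and 62.4 in the cKO at basal KCl. The list's median log2 difference was 0.02 at basal KCl and 0.03 after KCl (−0.08 with rescaling to the ribosomal list). Sex-linked genes, chosen after their values were seen, separated the genotypes: Xist, the RNA of the inactive X chromosome, stood at 83.3 and 78.1 FPKM in the wild-type libraries and at 0.14 and 0.29 in the cKO libraries. The Y-linked gene Eif2s3y stood at 0.052 and 0 in the wild-type libraries and at 32.9 and 39.0 in the cKO libraries. Sex therefore followed genotype in all 4 libraries, which applies to every genotype comparison given here.

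**Figure D1:**
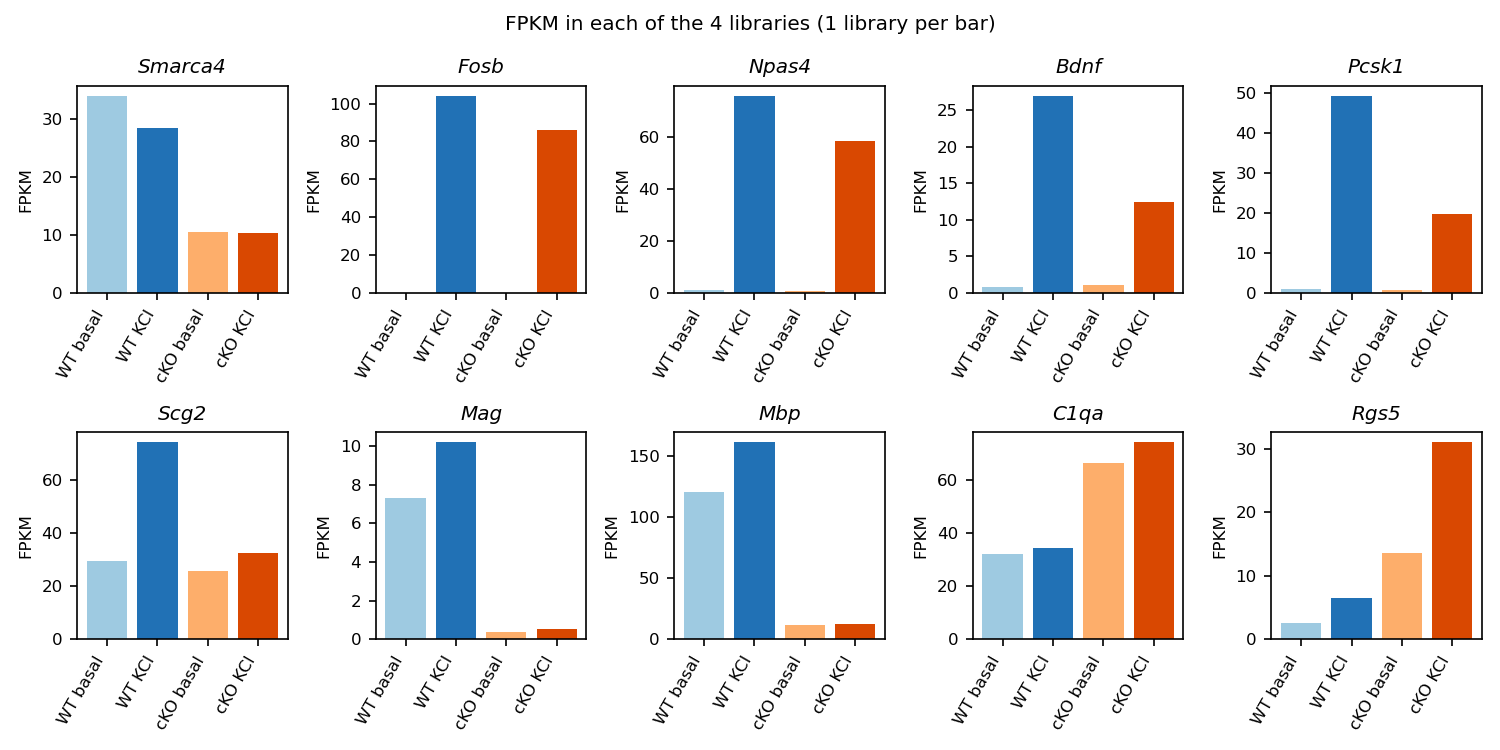
FPKM of 10 genes in each of the 4 libraries, 1 bar per library, each panel with its own axis from 0. Smarca4 stood at 34.0 and 28.5 in the wild-type libraries and at 10.5 and 10.4 in the cKO libraries, and Bdnf reached 27.0 after KCl in wild type and 12.4 in the cKO.

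The comparison of KCl with basal in wild-type neurons shows the response to depolarization. Immediate early genes, transcription factors and signalling genes that are switched on without new protein synthesis, were higher with KCl in 23 of 26 cases, none was lower, and 3 lay within 2-fold. The median log2 ratio of the list was 3.0, above all 10000 random matched lists. Fosb went from 0.11 to 104.1 FPKM, Fos from 2.40 to 203.4, Npas4 from 0.97 to 75.7 and Nr4a1 from 4.05 to 162.1. Egr1 was also higher (3.71 and 28.8), while Arc, a synaptic plasticity gene, stood at 0.64 and 1.52 FPKM. Late activity-regulated genes, many of which encode secreted or signalling proteins, were higher in 23 of 36 cases and lower in none, with a median log2 ratio of 1.33, above all random lists. Bdnf, a neurotrophin, stood at 0.73 and 27.0 FPKM, the prohormone convertase gene Pcsk1 at 0.93 and 49.3, Scg2 at 29.3 and 74.1, and Nptx2 at 1.21 and 5.39. Tnfrsf12a, a receptor of the TNF family, and Ctgf, a matricellular protein gene, were among the 10 highest ratios, at 2.91 and 92.1 FPKM and at 2.46 and 62.5 FPKM.

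The lowest ratios with KCl in wild type included genes of inhibitory interneurons. Of 14 measured interneuron markers 8 were at least 2-fold lower and none was higher, with a median log2 ratio of −1.15, below all random lists. The interneuron transcription factor gene Lhx6 stood at 17.3 FPKM in basal and 1.74 in KCl, the vesicular GABA transporter gene Slc32a1 at 17.5 and 2.83, and the GABA-synthesizing enzyme genes Gad1 at 28.4 and 7.96 and Gad2 at 8.11 and 1.58. Excitatory neuron markers had a median of −0.25 (0.28 with rescaling to the presynaptic list), with 2 of 15 lower, among them Bcl11b (10.7 and 2.79) and Neurod1 (14.1 and 5.48). Presynaptic genes had a median of −0.26 and glutamate receptor and postsynaptic genes of −0.22, which became 0.32 and 0.33 with rescaling to the presynaptic list. Of these, 1 of 21 presynaptic genes was higher (Sv2c) and 1 lower (Syn2), and 2 of 32 postsynaptic genes were lower (Nrxn3 and Dlg3). Ion channel genes had a median of −0.09 (0.40 with rescaling to the presynaptic list), with Kcna1 higher (2.63 and 7.79) and Scn2b lower (6.42 and 2.02) among 31. Over all genes, 672 were at least 2-fold higher and 439 lower, so 60.5% of the genes past this size were higher. This share was 25.8% with rescaling to the ribosomal list, which moved the median of all genes to −0.31, and 95.7% with rescaling to the presynaptic list, which moved it to 0.50.

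The same comparison in cKO neurons shows which of these responses were present with Smarca4 low. Immediate early genes were again higher in 23 of 26 cases and lower in none, with a median log2 ratio of 2.82. Fosb stood at 0.11 FPKM in basal and 86.3 in KCl, Fos at 3.69 and 224.1, Npas4 at 0.69 and 58.4, Egr1 at 5.68 and 48.8, and Arc at 0.44 and 2.41. Late genes were higher in 17 of 36 cases and lower in none, with a median of 0.84, and Bdnf stood at 1.12 and 12.4, Pcsk1 at 0.70 and 19.7, Scg2 at 25.8 and 32.3, and Nptx2 at 1.01 and 3.20. Thbs1, a matrix glycoprotein gene, was among the 10 highest ratios, at 8.03 and 216.7. Interneuron markers were lower in 8 of 14 cases, with a median of −1.22, and Lhx6 stood at 16.7 and 2.19. Excitatory neuron markers had a median of −0.55, with 3 of 15 lower, including Tbr1 (29.4 and 10.4). Presynaptic, postsynaptic and ion channel medians were −0.26, −0.32 and −0.24, and they became 0.28, 0.18 and 0.25 with rescaling to the presynaptic list. In all, 584 genes were higher and 410 lower, a share of 58.8% higher, against 14.6% with rescaling to the ribosomal list (all-gene median −0.46) and 93.4% with rescaling to the presynaptic list (0.49). Of the genes past 2-fold, 380 were higher in both genotypes, where 29.6 would be if the lists were independent, and 267 were lower in both, where 13.6 would be. Across the 13248 genes, which are not independent replicates, the responses had a Pearson correlation of 0.85 and a Spearman correlation of 0.87.

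**Figure D2:**
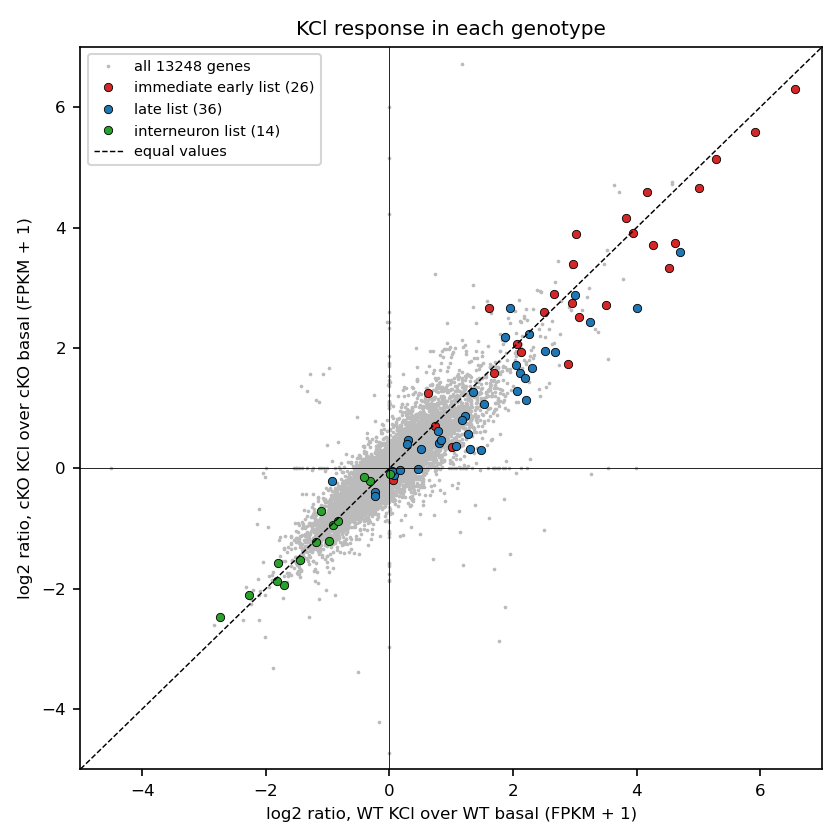
Log2 ratio of KCl over basal (FPKM + 1) in wild type on the horizontal axis and in the cKO on the vertical axis, 1 point per gene, with immediate early (26), late (36) and interneuron (14) genes in colour and a dashed line of equal values. Interneuron genes lay low in both genotypes (medians −1.15 and −1.22), and late genes lay mostly under the dashed line (31 of 36).

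The difference between these responses addresses the question in the series title, activity-dependent gene activation with and without Brg1. Late activity-regulated genes had the lower log2 response in the cKO, counted with its sign, in 31 of 36 cases, with a median log2 difference of −0.37, below all random lists. For each gene this difference equals the genotype difference after KCl minus that at basal KCl. The late medians of these were −0.30 and 0.09, so part of the smaller response came from a higher basal level. The differences were −1.35 for Bdnf, −1.19 for the neuropeptide gene Adcyap1, −1.10 for Pcsk1, −1.07 for Nrn1 and −0.99 for Scg2, while Ptgs2, the inducible cyclooxygenase gene, had a difference of 0.70. Immediate early genes differed less, with a median of −0.17, also below the central 95% of random lists, and a lower log2 response in 18 of 26. Among them Nr4a2 differed by −1.19, Egr4 by −1.16, Fosb by −0.27, Npas4 by −0.15, and Ier3 by 1.06. Random lists were matched on level and not on KCl response, so neither placement compares late or immediate early genes with other KCl-induced genes. Excitatory neuron markers had a median difference of −0.33, with 12 of 15 below 0, including Neurod2 (−1.09) and Neurod6 (−0.73). Lists outside activity and neurons lay on both sides: oligodendrocyte markers had a median difference of −0.30 with 9 of 10 below 0, cholesterol synthesis genes −0.16 with 12 of 17, and progenitor and cell cycle genes −0.11 with 12 of 17, while the medians were 0.19 for heat shock, 0.13 for ribosomal, 0.07 for glycolysis, 0.06 for microglial and 0.02 for astrocyte genes. With rescaling to the ribosomal list these 5 became −0.0004, −0.07, −0.11, −0.13 and −0.17, and the astrocyte median was also below 0 by the median ratio (−0.01) and the presynaptic list (−0.05). The postsynaptic adhesion gene Lrrtm1 (−1.30) and the potassium channel gene Kcna1 (−1.24) were among the 10 most negative, and their lists had medians of −0.08 and −0.15. Presynaptic genes had a median of 0.00, which lay between −0.17 and 0.00 under the rescalings. Responses were larger in the cKO for the chemokine gene Ccl2 (2.49), the G protein regulator gene Rgs16 (1.69), S100a6 (1.48) and the metalloproteinase inhibitor gene Timp3 (1.33), and vascular and fibroblast markers had a median difference of 0.25 with 11 of 11 above 0. Over the 672 genes at least 2-fold higher with KCl in wild type the median difference was −0.28, with 518 smaller in the cKO. Choosing genes on one response inflates that response: the 584 genes chosen on the cKO response had a median difference of 0.15, and the 577 chosen on the mean of both had −0.13, with 347 smaller in the cKO.

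The comparison of cKO with wild type at basal KCl shows differences present before depolarization. Genes of maturing oligodendrocytes, the myelin-forming cells, included some of the 10 lowest ratios. Mbp stood at 120.7 FPKM in wild type and 11.6 in the cKO, Mag at 7.29 and 0.36 and Cnp at 80.0 and 28.9, while Mog, a late myelin gene, stood at 4.72 and 3.96, and Olig1, expressed from the progenitor stage on, at 192.0 and 225.3. In this list 4 of 10 genes were lower, none was higher, and the median log2 ratio was −0.40. Microglial markers were higher in 5 of 12 cases and lower in none, with a median of 0.96 and all 12 above 0, for example Csf1r (12.5 and 29.7) and Fcer1g (15.1 and 36.5). Vascular and fibroblast markers were higher in 6 of 11 cases and lower in none, with a median of 1.31, including the pericyte gene Rgs5 (2.62 and 13.6) and Col3a1 (6.25 and 23.1). Progenitor and cell cycle genes had a median of 0.52 with 17 of 17 within 2-fold after 1 was added to both values. The deposited values of some cell cycle genes, such as Aurkb (1.69 and 4.13), differed by more than 2-fold. All cell cycle genes lay above 0, such as Ccna2 (7.03 and 14.4), and the 4 below 0 were all progenitor genes, such as Sox2 (67.8 and 52.3). Astrocyte markers had a median of −0.22 with 2 of 13 lower, S100b (8.34 and 1.34) and Ntsr2 (5.94 and 2.03), and interneuron and presynaptic medians were −0.25 and −0.18 with no member past 2-fold. Immediate early and late genes had medians of 0.00 and 0.09, with all 26 and all 36 members within 2-fold. The late median lay above the upper limit of the central range of random lists (0.063), with 25 of 36 members above 0. A higher basal level in the cKO lowers its KCl ratio by construction. Postsynaptic, ion channel and excitatory neuron medians were −0.05, −0.01 and 0.01. Of 15 excitatory neuron markers 1 was at least 2-fold lower, Nrgn (170.6 and 81.4), and none was higher. The postsynaptic median became 0.02 and 0.11, and the ion channel median 0.06 and 0.13, with rescaling to the ribosomal and the presynaptic list, and the ion channel median was 0.0007 with the upper quartile. Over all genes, 124 were higher and 73 lower, and 62.9% were higher, against 76.0% with rescaling to the presynaptic list, which moved the median of all genes to 0.17. With unnamed genes and small RNAs left out the lower genes numbered 31, and 73.0% were higher.

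The comparison of cKO with wild type after KCl shows the genotypes in the depolarized state. The oligodendrocyte genes were again lower in 4 of 10 cases, with a median of −0.75, and Mbp stood at 161.5 FPKM in wild type and 12.9 in the cKO, and Mag at 10.2 and 0.51. Microglial markers were higher in 9 of 12 cases with a median of 1.10, and vascular and fibroblast markers in 8 of 11 with a median of 1.79, with no member lower in either list. Spp1, a secreted phosphoprotein gene, stood at 145.4 and 698.6, and Rgs5 at 6.55 and 31.0. Excitatory neuron markers had a median of −0.41, 14 of 15 lay below 0 and 2 were at least 2-fold lower, Nrgn (154.1 and 58.0) and Neurod2 (78.4 and 38.3). Late genes had a median of −0.30 with 4 of 36 lower, namely Pcsk1 (49.3 and 19.7), Scg2 (74.1 and 32.3), Adcyap1 (9.91 and 3.95) and Bdnf (27.0 and 12.4). Immediate early genes had a median of −0.08, which became 0.05 with rescaling to the presynaptic list, with Ier3 higher and Egr3, Egr4 and Fosl2 lower. Presynaptic, postsynaptic and ion channel medians were −0.22, −0.16 and −0.15, interneuron and astrocyte medians −0.23 and −0.24, and the median of progenitor and cell cycle genes 0.33, where the 4 of 17 below 0 were all progenitor genes, such as Sox2 (log2 ratio −0.48), and every cell cycle gene lay above 0. Over all genes, 248 were higher and 125 lower, and 66.5% were higher, against 52.7% with rescaling to the ribosomal list and 78.0% with rescaling to the presynaptic list, which moved the median of all genes to 0.15. With unnamed genes and small RNAs left out the lower genes numbered 69, and 75.4% were higher. The comparisons at basal KCl and after KCl share no library. In both, 79 genes were higher, where 2.32 would be if the lists were independent, and 34 were lower, where 0.69 would be. The comparisons are not independent repeats, since sex followed genotype in both. Eif2s3y was among the genes higher in both and Xist among those lower in both. Across genes the comparisons had a Pearson correlation of 0.57 and a Spearman correlation of 0.45.

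**Figure D3:**
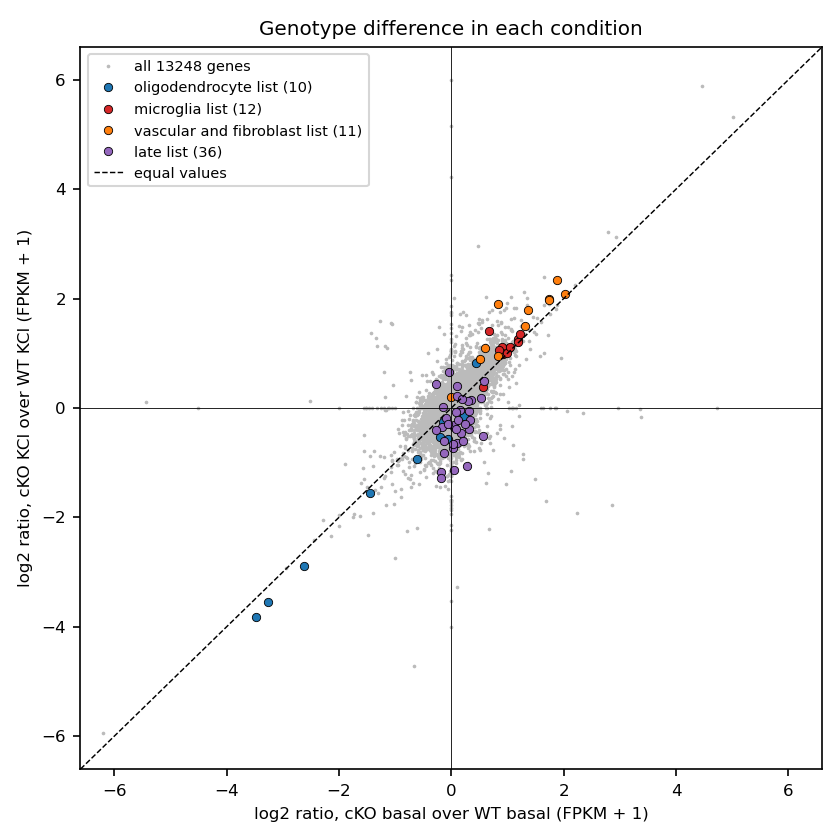
Log2 ratio of cKO over wild type (FPKM + 1) at basal KCl on the horizontal axis and after KCl on the vertical axis, 1 point per gene, with oligodendrocyte (10), microglia (12), vascular and fibroblast (11) and late (36) genes in colour and a dashed line of equal values. The microglial medians were 0.96 and 1.10, and the 4 lowest oligodendrocyte genes lay low in both conditions.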

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

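The tests of the neuronal share, the excitatory neuron share and the strength of depolarization were chosen only after the result was seen, and so were rescaling to the presynaptic list and choosing genes on the mean of both responses. Of 247 named genes, 15 had opposite signs in a pair of comparisons, with both sides at 0.25 or more on the log2 scale. These differences were not tested.

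The KCl response had opposite signs in the genotypes for 5 genes. Rtn4rl2, a Nogo receptor family gene, had log2 responses of 0.34 in wild type and −0.98 in the cKO, a difference of −1.32. Lrrtm1 had 0.89 and −0.41, a difference of −1.30, and Lrrtm2 had 0.33 and −0.48, a difference of −0.81, and with rescaling to the presynaptic list the signs of these 2 genes were no longer opposite. Neurod2, an excitatory neuron transcription factor gene, had 0.55 and −0.55, a difference of −1.09. Aif1, a microglial gene, had −0.34 and 0.40, a difference of 0.74, and the opposite signs were lost with rescaling to the ribosomal or the presynaptic list.

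The genotype difference had opposite signs at basal KCl and after KCl for 10 genes, in all 4 rescalings. For 9 of these genes the cKO was higher at basal KCl and lower after KCl, and the change between conditions was −1.35 for Bdnf, −1.32 for Klf5, −1.19 for Nr4a2, −1.18 for S1pr3, −1.07 for Nrn1, −0.87 for Junb, −0.73 for Neurod6, −0.68 for Tbr1 and −0.67 for Pmaip1. Timp3 had the reverse order, with a change of 1.33.

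Late activity-regulated genes had a smaller KCl response in the cKO libraries (median −0.37). That list was fixed beforehand, so choosing genes on these responses does not account for it. Genes chosen on the mean of both responses had a median difference of −0.13, with quartiles of −0.38 and 0.24 and 347 of 577 smaller in the cKO. This median lay beyond 3 times the random-list SD of 0.011. That SD gives the spread neither of induced genes nor of cultures, because random lists were not chosen on KCl response and each group had 1 library. It therefore cannot decide whether the choice of genes accounts for the smaller response of induced genes. A lower share of neuronal RNA in the cKO KCl library would lower presynaptic genes alike. Their median difference lay 0.37 above the late list's, with an SD of 0.19 over members. The presynaptic list thus argues against it, and interneuron markers (−0.03) also moved little. Postsynaptic (−0.08) and ion channel (−0.15) medians, however, lay below the central 95% of random lists, so a lower neuronal share is not excluded. A uniformly weaker depolarization would also bring genes lower with KCl toward 0, but their median cKO response was 0.98 of the wild-type one over 386 genes. The upper quartile of their differences (0.20) lay below the 0.45 that the late list's ratio of 0.63 requires. Whether their fall scales with depolarization as the late genes' rise does was not examined, so these values argue against a weaker depolarization only on that condition. The immediate early list alone left a weaker depolarization open. Its ratio of 0.94 exceeded the late list's by 0.31 with a 95% interval over resampled genes of 0.06 to 0.68, against a bound of 0.18. A lower share of excitatory neurons in the cKO KCl library may account for the smaller late response. That list's median difference of −0.33 was as low as the late list's within an SD of 0.33 over members. This SD is nearly as large as the late list's difference, so the test could hardly have failed. Members did not move together, from −1.09 for Neurod2 to 0.11 for Cux2, with 3 of 15 above 0, so the question stays open. Dependence on Brg1 was not tested apart from sex, which followed genotype.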

How the results depend on the processing

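No paired analysis was possible because the groups share only 1 replicate number, which was given in accession order and pairs no libraries, and the results come from no test. With 1 library per group none could be left out of a comparison, and an additive model of genotype and KCl, which has 1 residual degree of freedom, was not fitted. Rescaling to the presynaptic list, leaving out X and Y genes or unnamed genes and small RNAs, and choosing genes on the cKO response or on the mean of both were chosen after seeing the data. Depth limits genes near 1 FPKM most, and no setting changed the sign of a named gene whose ratio was past 2-fold. For a single comparison none could. Constants and filters cannot change a sign, and every rescaling shifted ratios by less than 2-fold. Named genes with ratios past 2-fold had 2498 values under other settings. Of these, 1604 moved by less than a margin drawn from their counting interval, and 894 were not shown to. The 894 include 15 values without a filter, a setting that leaves a gene's ratio unchanged, so they are not all shifts. Some named genes, such as Ctgf, have no counting interval. Of 960 list medians, 79 changed sign, 19 of them with a main median outside the central 95% of random lists and 60 with one inside it. Except where stated, the cause was not tested.

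Counts are given in the order higher and lower with KCl in wild type, higher and lower with KCl in the cKO, higher and lower in the cKO at basal KCl, higher and lower in the cKO after KCl, and higher and lower in both genotype comparisons. A smaller size rule or added constant admits more genes by construction. With an added constant of 0.1 the counts were 1029, 838, 878, 787, 377, 132, 486, 240, 248 and 65, and the median difference in response was −0.31. With a constant of 5 they were 261, 78, 222, 89, 29, 19, 73, 37, 21 and 14, and the median was −0.25. With a size of 1.5-fold they were 1681, 1693, 1518, 1473, 523, 192, 736, 440, 384 and 96, and the median was −0.18. With a size of 4-fold they were 114, 20, 102, 24, 14, 12, 19, 20, 6 and 9, and the median was −0.31.

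With a filter of 5 FPKM fewer genes were examined: 42 were lower in the cKO at basal KCl, 162 were higher and 83 lower after KCl, the median difference was −0.25, and the sonic hedgehog median at basal KCl became 0.013. In the cKO response to KCl that filter turned the neuropeptide median from −0.10 to 0.04 and the sonic hedgehog median from −0.01 to 0.20. With unnamed genes and small RNAs left out, 31 genes were lower in the cKO at basal KCl and 69 after KCl, and the median difference was −0.25. Rescaling by the median ratio gave a median difference of −0.30. Without a filter, with the upper quartile and with X and Y genes left out, each of the 10 counts stayed within 1.5 times its main value.

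Rescaling to the ribosomal list gave 395 higher and 1135 lower with KCl in wild type, 272 and 1595 in the cKO, 165 higher in the cKO after KCl, and a median difference of −0.49. By construction it lowers every KCl ratio. In the cKO response to KCl the medians became −0.14 for cholesterol synthesis, −0.11 for microglia, −0.084 for p53 targets and −0.044 for ribosomal genes. The difference in response became −0.00040 for heat shock and −0.068 for ribosomal genes, and the ribosomal genotype median after KCl became −0.0057.

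Rescaling to the presynaptic list raises every KCl ratio by construction, and since it equalizes the list's median level it overshot the list's own median ratio, which became 0.32 in wild type and 0.28 in the cKO. It gave 2033 higher and 92 lower with KCl in wild type, 1783 and 125 in the cKO, and a median difference of −0.18. With KCl in wild type the medians became 0.33 for postsynaptic genes, 0.28 for excitatory neurons and 0.18 for neuropeptides, and in the cKO 0.18 for postsynaptic genes, 0.25 for ion channels and 0.22 for matrix and guidance genes. The genotype median at basal KCl became 0.050 for sonic hedgehog genes, and after KCl 0.052 for immediate early genes and 0.042 for matrix and guidance genes.

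The median difference in response over KCl-induced genes was −0.28 with genes chosen on the wild-type response, 0.15 with genes chosen on the cKO response and −0.13 with genes chosen on the mean of both. The reversal follows from the choice, since selecting on one response inflates it.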

Other observations

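The tests of explanations in this part, except the spread of the microglial markers, and rescaling to the presynaptic list were chosen only after the result was seen. Cholesterol synthesis genes had median log2 ratios of 0.69 in wild type and 0.40 in the cKO (−0.14 in the cKO with rescaling to the ribosomal list), with 3 and 1 of 17 at least 2-fold higher and 1 and 0 lower. Cyp51 stood at 84.4 FPKM in basal and 191.2 in KCl in wild type, and Mvd at 82.5 and 36.9. Their genotype medians were −0.05 at basal KCl (0.03 and 0.13 with rescaling to the ribosomal and the presynaptic list) and −0.21 after KCl. Glycolysis and glucose uptake genes had medians of 0.50 and 0.51 with KCl, with 3 and 2 of 18 higher, including the lactate transporter gene Slc16a3 (4.66 and 11.7 in wild type), and medians of −0.31 and −0.30 in the genotype comparisons, where 17 and 16 of 18 lay below 0. Heat shock genes had medians of 0.41 and 0.60 with KCl, with 5 of 12 higher in each genotype, such as Bag3 (4.22 and 18.1 in wild type, 4.76 and 17.5 in the cKO). Their difference in response was 0.19, or −0.0004 with rescaling to the ribosomal list, and their genotype medians were −0.03 and 0.15, the first becoming 0.03 and 0.13 with rescaling to the ribosomal and the presynaptic list. Hspa1a and Hspa1b are near-identical copies, and how reads were assigned to them was not examined. Endoplasmic reticulum stress genes had medians of 0.15 and 0.22 with KCl (−0.18 and −0.28 with rescaling to the ribosomal list) and of 0.03 and 0.04 between genotypes (the latter −0.06 with that rescaling), and the KCl medians lay inside the central 95% of random lists, with 4 of 19 genes higher in each genotype. Among them were Ppp1r15a (4.59 and 61.2 in wild type), which encodes a phosphatase subunit, and the chaperone gene Hspa5 (86.9 and 271.3). The p53 target medians were 0.33 and 0.44 with KCl (−0.08 in the cKO with rescaling to the ribosomal list) and 0.18 and 0.08 between genotypes (the latter −0.03 with that rescaling), with Cdkn1a at 18.1 and 40.7 in wild type.

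Among the remaining lists, progenitor and cell cycle genes had medians of 0.52 and 0.47 with KCl, and Vim, an intermediate filament gene, stood at 63.0 and 319.2 in wild type. Vascular and fibroblast markers had medians of 0.70 and 1.13 with KCl. With rescaling to the ribosomal list the following KCl medians changed sign: microglia 0.17 and 0.38 (−0.16 and −0.11), astrocytes 0.16 and 0.21 (−0.18 and −0.32), oligodendrocytes in wild type 0.18 (−0.15) and interferon-stimulated genes in wild type 0.20 (−0.09). The oligodendrocyte median in the cKO was −0.08 (0.37 with rescaling to the presynaptic list), and 7 interferon-stimulated genes had a median of 0.66 in the cKO and genotype medians of 0.15 and 0.35. Matrix and guidance genes had KCl medians of −0.15 and −0.20 (0.42 and 0.22 with rescaling to the presynaptic list) and genotype medians of −0.01 and −0.08 (0.14 and 0.04 with that rescaling, and 0.05 for the first with rescaling to the ribosomal list). Neuropeptide genes had KCl medians of −0.25 and −0.10 (0.18 and 0.42 with rescaling to the presynaptic list, and 0.04 for the second with a filter of 5 FPKM) and genotype medians of −0.08 and −0.06 (0.0003 and 0.08), with Vgf at 7.33 and 66.2 in wild type. Sonic hedgehog genes had KCl medians of 0.06 and −0.01 and genotype medians of −0.10 and −0.20. Of these the first became −0.01 with the upper quartile and −0.25 with the ribosomal rescaling, the presynaptic rescaling gave 0.38 for the second and 0.05 for the third, and a filter of 5 FPKM gave 0.20 for the second and 0.01 for the third. BAF subunits had KCl medians of −0.08 and −0.05 (0.47 and 0.48 with rescaling to the presynaptic list). Ribosomal protein genes, a family with many pseudogenes, had KCl medians of 0.37 and 0.48 and genotype medians of 0.01 and 0.11. Rescaling to the list itself gave −0.04 in the cKO and −0.01 for the genotype difference after KCl. Reference genes had KCl medians of 0.16 and 0.02 (−0.17 and −0.50 with rescaling to the ribosomal list, and −0.05 for the second with the upper quartile) and genotype medians of 0.01 and 0.06 (the latter −0.05 with the ribosomal rescaling). Their member Tubb3, a neuronal tubulin gene, stood at 1187 and 278.4 FPKM in wild type and at 1175 and 283.7 in the cKO, and Tubb5 at 1118 and 541.7 in wild type. Of tubulin genes chosen after their values were seen, Tubb4 stood at 249.2 and 64.0 in wild type and Tubb6 at 6.44 and 29.3. None of the 8 erythroid genes with a value of their own reached 1 FPKM. Genes of general metabolism also stood near 0, Hmgcs1 at 0 in all 4 libraries, Gapdh at 0.07 to 0.25 and Ppia at 0.06 to 0.24, so a value near 0 in this table does not show that a gene was not expressed.

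Sex followed genotype in all 4 libraries. Maturing oligodendrocyte genes were lower in both cKO libraries, except Mog, which lay within 2-fold (log2 ratios of −0.21 and −0.53). Fewer cells of the whole lineage would lower progenitor genes alike. The median of Olig1, Olig2 and Pdgfra lay 1.97 above that of Mbp, Mag, Cnp and Mog at basal KCl and 1.96 above after KCl. The SD over the maturing genes was 1.35 in each comparison. The progenitor medians themselves were −0.06 and −0.26. Of list members in neither set, Sox10 had log2 ratios of −0.60 and −0.93, and Cspg4 of 0.45 and 0.82. These values argue against an equal fall of all lineage genes, but some loss of lineage cells is not excluded. A difference between embryos other than Brg1, such as sex, litter or culture, could account for the lower maturing genes and cannot be told apart. Xist had a log2 ratio of −6.21 between cKO and wild type, and each genotype came from 1 sex.

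Microglial and mural or fibroblast genes were mostly higher in both cKO libraries. All 12 microglial markers lay above 0 in both comparisons, as did 10 of 11 vascular and fibroblast markers at basal KCl and 11 of 11 after KCl. At basal KCl only 5 of 12 and 6 of 11 were at least 2-fold higher. A lower share of neuronal RNA would raise every other cell type alike, but the microglial median lay 1.18 above the astrocyte median at basal KCl and 1.34 above after KCl, with SDs of 0.63 and 0.57 over astrocyte markers. More microglia in the cKO cultures may account for the microglial part, since the markers of the fixed list were higher by a similar factor, with an interquartile range of 0.21 after KCl and 0.19 at basal KCl against medians of 1.10 and 0.96. At basal KCl Ctss stood at 32.9 and 69.1 FPKM in wild type and the cKO, but Lyz2, outside the list and chosen after its values were seen, was 3.17-fold higher (84.0 and 266.5) and Cd14 3.55-fold, which a single factor does not cover, and the mural and fibroblast part was not examined by this test. A difference between the embryos other than Brg1 cannot be told apart for either part, since Ddx3y, on the Y chromosome, had a log2 ratio of 4.46.

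Genes with 2 or fewer annotated exons made up 6.31% of 11331 genes, 12.4% of those higher with KCl in wild type and 23.9% of those lower, and in the cKO 11.8% and 26.8%. Across genes, the Spearman correlation of the difference in KCl response was −0.19 with transcript length and 0.08 with GC content. Among genes under 1 FPKM in every library, 3574 were above 0 in the wild-type basal library and 4087 in the wild-type KCl library, and 3605 and 4123 in the cKO. Pisd-ps1, a pseudogene, stood at 0.0033 FPKM in the wild-type basal and 8.65 in the wild-type KCl library and at 0.073 and 0.0042 in the cKO, and Atp6v0c, which has paralogous copies, stood at 3.75 in wild type and 16.6 in the cKO at basal KCl. How reads were assigned between copies was not examined.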
